A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

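RNA of a budding yeast strain whose Nab2 protein carried a heat-inducible degron (nab2-td) and of a wild-type control was measured at 0, 30 and 75 min after a shift from 26 °C to 37 °C. The labels describe cells grown in glucose with copper, moved to galactose without copper to express Ubr1, and then shifted in temperature. They give 2 control and 3 nab2-td arrays at each time, 15 in all, of a whole-genome yeast expression platform hybridised with biotin-labelled cRNA from total RNA.

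The deposited table holds 1 log2 expression value per probe set and array. Per the labels, the authors used GCOS, RMA and limma, with no version given. The deposited values were used as they stand, with no further normalisation in the fit reported first. In them the median of the tested genes lay between 10.2 and 10.26 on all 15 arrays. Higher and lower are therefore relative to the other transcripts, and a change of all transcripts together cannot be seen. No raw images and no detection calls were available, so signal over background was judged from probe sets of genes outside the S. cerevisiae gene table. The number of arrays limits the precision: with 6 groups the model had 9 residual degrees of freedom per gene, and 11.8 after moderation.

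The table has 10928 probe sets. Of these 7244 carried 1 gene symbol, 1 carried several and 3683 carried none, of which 166 were control probe sets and 3517 were not. Gene names were matched to a table of S. cerevisiae genes of the R64 assembly, which was used for names, neighbours and lengths, and 5498 probe sets matched. Where a gene had several probe sets (47 genes), the one with the highest mean over all arrays was used, and no such gene had probe sets called in opposite directions at 75 min. This left 5449 genes, 115 of them read by probe sets that the platform marks as shared between sequences. Another 1747 probe sets named a gene that is not in that table, and they were left out of the gene tests. The annotation gave no introns, and no genome sequence was at hand.

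All 15 arrays entered 1 linear model with a mean for each of the 6 groups (limma 3.58.1 in R 4.3.3, lmFit and eBayes). From it 9 contrasts were taken: nab2-td against wild type at each time, 30 and 75 against 0 min in each strain, and the interactions of strain with each later time. Tests were two-sided, p values were adjusted by Benjamini-Hochberg over all genes within a contrast, and genes with adjusted p under 0.05 were called. The samples, contrasts, gene lists, naming rule and the first set of other settings were fixed before the data were examined.

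Gene lists were tested with camera at its preset correlation of 0.01, and adjusted over the 27 lists with at least 5 measured members within each contrast, 243 tests in all. Beside each count over all genes stands the count adjusted over the list alone. The lists were 128 cytosolic ribosomal protein genes, 137 ribosome biogenesis genes, 15, 7 and 19 genes of RNA polymerases I, II and III, 29 of nuclear mRNA export, 25 of 3′-end formation, 23 of the exosome, TRAMP and Nrd1 complexes, 25 Hsf1 chaperones, 35 Msn2/4 stress genes, 6 GAL genes, 7 copper-regulated genes, 18 of the iron regulon, 16 of glycolysis, 16 of the TCA cycle, 32 of the respiratory chain and ATP synthase, 29 Gcn4 amino acid genes, 33 of the proteasome, 14 of the unfolded protein response, 25 translation factors, 7 core histones, 19 G1/S, 12 G2/M, 7 a-cell, 9 haploid, 14 sporulation and 7 stationary-phase genes. A list of alpha-cell genes had 4 measured members and was not tested, and lists of small RNA and tRNA genes had 0. The lists share no gene. Camera with a correlation estimated for each list, and fry, a rotation test of the list itself, were run beside it. The estimated correlations rest on 9 residual degrees of freedom.

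The naming rule took, for each strain contrast, the 10 genes with the largest positive and the 10 with the largest negative difference among those called, with arrays of the groups that did not overlap and with a gene symbol. For the other contrasts it took 5 per direction, without the non-overlap condition for the interactions. It also took up to 4 members with the largest absolute change per list, and always NAB2, UBR1, URA3, HIS3, GAL1 and CUP1-1. Of the genes with near-identical copies, CUP1-1 and PHO11 are named with that limit, and others, such as ribosomal protein and histone genes, are not marked. Shared probe sets read 24 of the 128 ribosomal protein genes and 2 of the 7 core histone genes. The text describes part of the genes the rule took.

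These settings were a fit of only the arrays of the groups compared, a block for the replicate number, limma array weights, a trended and robust variance model, all probe sets in place of 1 per gene, a minimum absolute log2 difference of 1, median centring, quantile normalisation and cyclic loess over the tested genes, leaving out 88 dim genes (mean below 4.38, the 95th percentile of the probe sets of other genes), leaving out 3 arrays whose description carries a suffix, and leaving out each of the 15 arrays in turn. The array weights stopped before full convergence. After seeing the data, 3 were added: leaving out the wild-type arrays labelled 0 min replicate 2 and 30 min replicate 2, leaving out all 4 wild-type arrays labelled 0 and 30 min, and a replicate block with the numbers of the wild-type arrays labelled 30 min exchanged. Labels were never reassigned. Where a setting left 1 array in a group, its spread was taken to be that of the other groups.

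The pipeline was tested on simulated data with known changes. Noise was drawn independently for each gene and array, with the gene's spread pooled over the 6 groups. For nab2-td against wild type at 75 min the pipeline recovered 51.6% of changes of 0.5 log2 units, 96.3% of 1 and 100% of 2, with 9 false calls among 5249 unchanged genes. For nab2-td at 75 against 0 min the shares were 58.9%, 88.1% and 100%, with 5 false calls. In the data the median spread ran from 0.044 log2 units (wild type at 75 min) to 0.183 (wild type labelled 0 min). The shares and false calls therefore hold for even, independent noise and not for these arrays. Permutation tests used 100000 permutations. Correlations across genes describe the genes and treat none as a replicate.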

Results

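The series compared a budding yeast strain in which Nab2, an essential nuclear poly(A)-binding protein, carried a heat-inducible degron (nab2-td) with a wild-type control that held the same galactose-driven ubiquitin ligase gene UBR1. Total RNA was profiled at 0 min (26 °C), and at 30 and 75 min after the shift to 37 °C. The control had 2 arrays and nab2-td 3 arrays at each time, 15 in all. Within a group, the lowest Pearson correlation between arrays across 5449 genes was 0.9901, 0.9897 and 0.9964 for nab2-td at 0, 30 and 75 min, and 0.9979 for the wild type at 75 min. It was 0.9677 for the wild-type arrays labelled 0 min and 0.9678 for those labelled 30 min. The wild-type array labelled 0 min replicate 1 lay closest to the array labelled 30 min replicate 2 (r = 0.9981), and the array labelled 0 min replicate 2 lay closest to the array labelled 30 min replicate 1 (r = 0.9981). The median standard deviation was 0.183 and 0.18 log2 units in those groups, against 0.044 in the wild type at 75 min and 0.1, 0.103 and 0.075 in nab2-td. The labels were kept as deposited. After the data had been seen, every comparison was also run with the arrays labelled 0 min replicate 2 and 30 min replicate 2 set aside. That choice rested on the profiles themselves, so its counts are no independent evidence of a wild-type response.

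**Figure D1:**
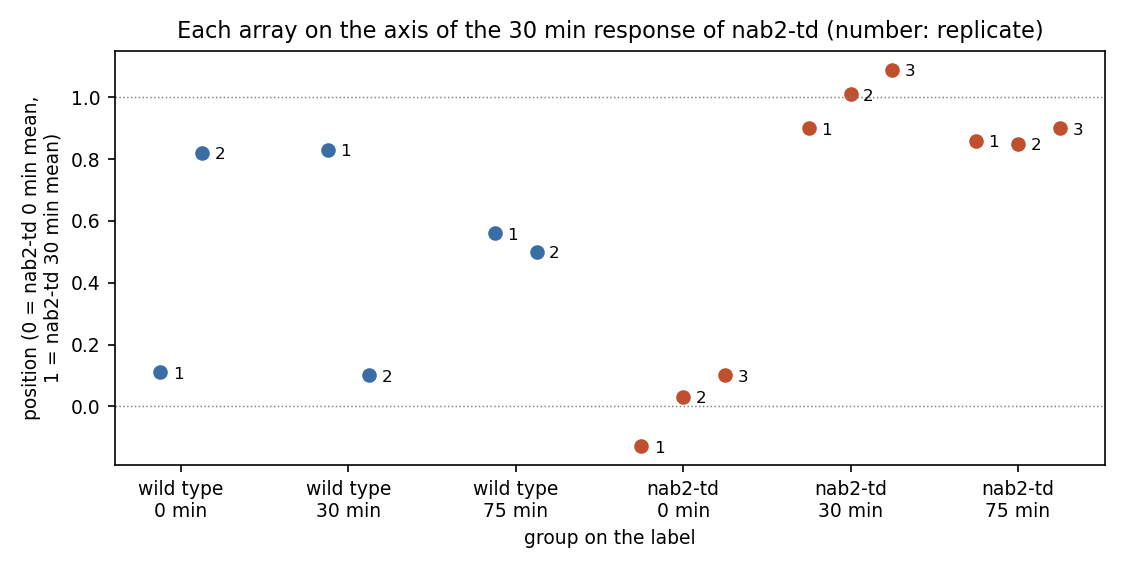
Position of each of the 15 arrays (y axis, no unit) on the axis from the mean of the nab2-td arrays at 0 min (position 0) to their mean at 30 min (position 1), by the group on the label (x axis); points are arrays and the number beside each is its replicate. The wild-type arrays labelled 0 min sit at 0.11 and 0.82, those labelled 30 min at 0.83 and 0.1, and those labelled 75 min at 0.56 and 0.5.

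Of the construct genes, NAB2 and URA3 separated the strains on every array. NAB2 transcript, which the construct places under the CUP1 promoter, was higher in nab2-td by 1.15 log2 units at 0 min (standard error, SE, 0.09; limma adjusted p = 0.00012), 1.66 at 30 min (SE 0.09, adjusted p = 1.9e-06) and 1.62 at 75 min (SE 0.09, adjusted p = 2.4e-07). All 3 nab2-td arrays lay above both wild-type arrays at each time. URA3, the selection marker of the degron cassette, was higher by 1.54, 1.25 and 1.56 log2 units (SE 0.15 each; limma adjusted p = 0.00058, 0.00054 and 9.8e-06). The array measures transcript, so these values carry no information on the amount of Nab2 protein. UBR1 differed by -0.2, 0.12 and -0.28 log2 units (adjusted p = 0.48, 0.62 and 0.13), the last with adjusted p = 0.0089 without the arrays set aside, and GAL1, the galactokinase gene, by -0.18, 0.17 and 0.04 (adjusted p = 0.44, 0.37 and 0.81). CUP1-1, read by a probe set shared between near-identical metallothionein copies, differed by -0.06, 0.01 and -0.08 (adjusted p = 0.66, 0.97 and 0.37). The group means of CUP1-1 (14.5 to 14.62) and of GAL1 (up to 14.5) lay near the highest value of the arrays (14.82 to 14.86), so a difference in either can be hidden. HIS3, the marker beside UBR1 in both strains, was 0.38 log2 units higher at 75 min (SE 0.12, limma adjusted p = 0.021) and did not pass at 0 min (0.28, adjusted p = 0.28) or 30 min (0.13, adjusted p = 0.53). With only the arrays of the groups compared in the model, NAB2 at 0 min and URA3 at 0 and 30 min missed the threshold, which left 3 of the 6 calls of these genes. UBR1 passed at 30 min without the wild-type array labelled 30 min replicate 1 (0.39), as did GAL1 (0.37), and at 75 min without either array labelled 30 min (-0.28 in both). The HIS3 call at 75 min was lost without the wild-type array labelled 75 min replicate 1 (adjusted p = 0.13) or 2 (0.077), or without nab2-td replicate 2 (0.07) or 3 (0.057).

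**Figure D2:**
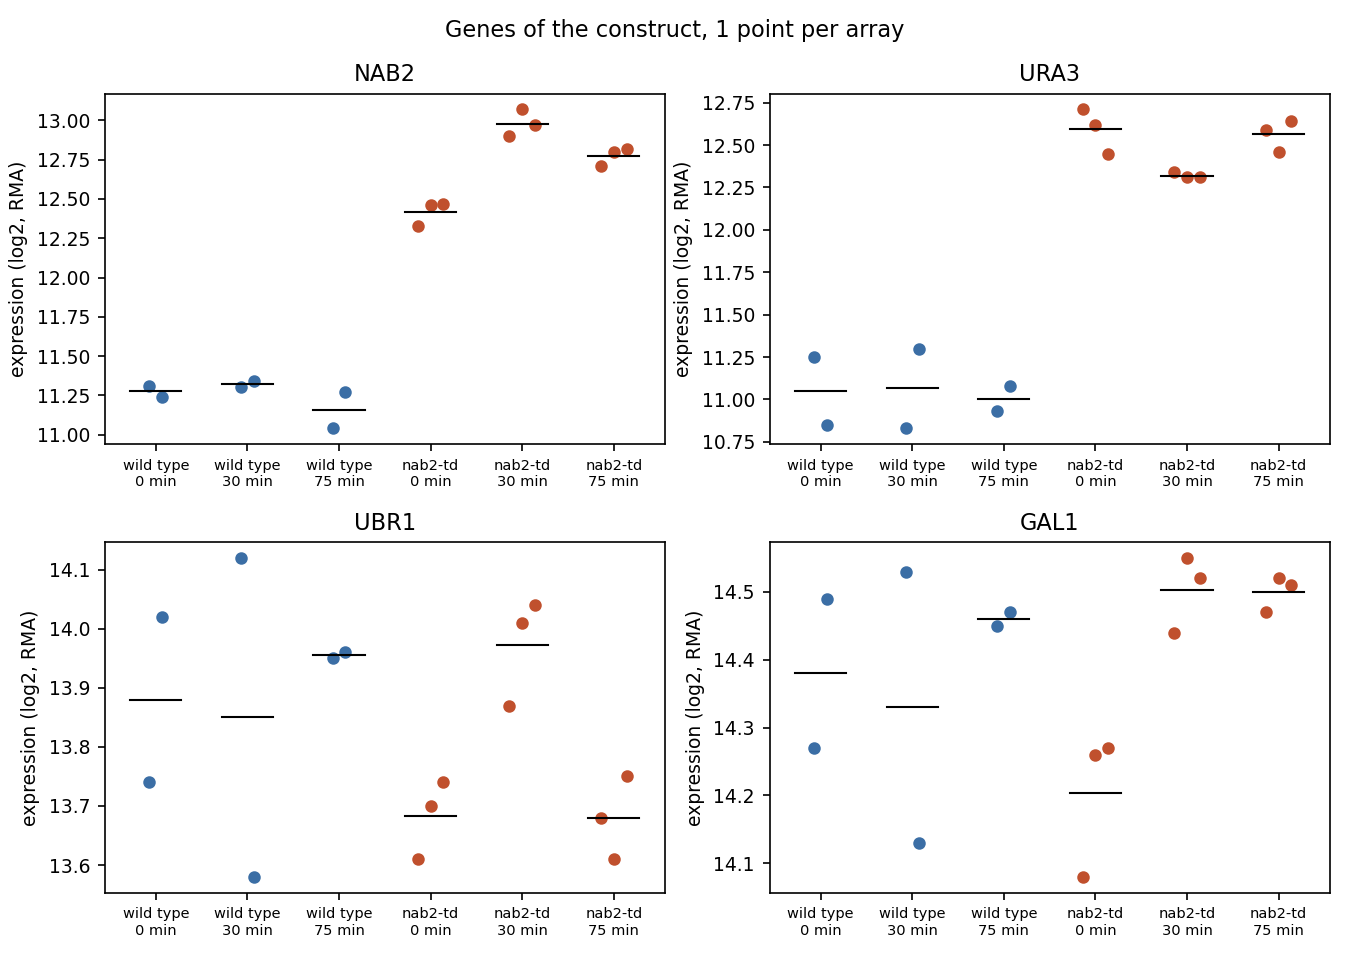
Level (y axis, deposited log2 RMA value) of NAB2, URA3, UBR1 and GAL1 in each of the 6 groups (x axis); points are arrays and lines are group means. NAB2 averaged 11.27, 11.32 and 11.15 in the wild type and 12.42, 12.98 and 12.78 in nab2-td at 0, 30 and 75 min.

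Before the shift, NAB2 and URA3 were the genes that limma called between the strains, 2 of 5449, both higher in nab2-td. At unadjusted p under 0.05 there were 850. When the wild-type arrays set aside after seeing the data were left out, 3 genes were called: NAB2, URA3 and EGO4, at 1.05 log2 units (adjusted p = 0.036). EGO4, singled out after its value was seen, stood at 0.2 (adjusted p = 0.83) with all arrays. No member of any gene list passed the test at 0 min over all genes. Within the iron regulon, genes of iron uptake driven by Aft1, 5 of 18 members were higher when adjusted over the list alone. Its median was 0.21 log2 units (camera adjusted p = 0.00015; adjusted p = 0.058 with an estimated correlation), and 0.24 without the 2 arrays (adjusted p = 0.00013). Camera also placed 8 other lists apart at 0 min: ribosomal proteins (median 0.22, adjusted p = 5e-12), translation factors (0.23, 0.00074), G2/M genes (0.27, 0.00074), glycolysis (0.07, 0.015), Hsf1 chaperones (-0.56, 6.2e-07), Msn2/4 stress genes (-0.33, 0.0014), the proteasome (-0.28, 1.2e-10) and stationary-phase genes (-0.4, 0.016). In each of these the estimated correlation gave adjusted p = 0.85. Adjusted over the list alone, 3 stationary-phase genes were lower and no member of the other 7 passed. Without the array labelled 0 min replicate 2 the medians were -0.01, -0.02, 0.05, 0.01, -0.09, 0.12, -0.12 and -0.22 in the same order, and only the proteasome was still called in its direction. Other lists were called when both arrays set aside were left out: ribosome biogenesis (-0.34, adjusted p = 3.6e-28), RNA polymerase I (-0.25, 0.0033), RNA polymerase III (-0.09, 0.016), exosome, TRAMP and Nrd1 genes (-0.16, 0.00012), Gcn4 amino acid genes (-0.16, 0.00098), copper-regulated genes (0.35, 0.0059), a-cell genes (0.14, 0.027) and, upwards, Msn2/4 genes (0.0059). No member was called in any. Cyclic loess also ended the glycolysis call (0.04). The gene count rose to 160 without the array labelled 0 min replicate 1 and to 201 without nab2-td replicate 3. Leaving out the 3 arrays with a suffix gave 1836, 844 higher and 992 lower.

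At 30 min after the shift, a small set of genes differed between the strains, and more were lower than higher in nab2-td. RRT5 was 3.3 log2 units higher (SE 0.22, limma adjusted p = 1.4e-05), and the meiotic genes REC102 and SPO19, which act in recombination and in prospore formation, were higher by 1.53 (SE 0.19, adjusted p = 0.00071) and 1.42 (SE 0.16, adjusted p = 0.00041). The wild-type mean of SPO19 (3.51) lay below the mark for dim genes (4.38), so its value is a lower bound. HRP1, a poly(A) RNA-binding subunit of the 3′-end cleavage machinery, was higher by 1.2 (SE 0.14, adjusted p = 0.00059), and RNA14, another subunit, by 0.93 (SE 0.14, adjusted p = 0.0026). THP3 was lower by 1.22 on the log2 scale (-1.22, SE 0.18, adjusted p = 0.0026), YOS1, which acts between the endoplasmic reticulum and the Golgi, stood at -1.07 (SE 0.1, adjusted p = 0.00015), and UBC12, the enzyme that conjugates Rub1, at -1.05 (SE 0.14, adjusted p = 0.0014). The other genes with the largest falls were ARP10 (-1.1), YSY6 (-1.1), TSC3 (-1.02), TRI1 (-1.01), HMRA1 (-1), GPI15 (-1) and NCE101 (-1).

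In all, limma called 330 genes at 30 min, 90 higher and 240 lower in nab2-td. By 2-fold or more, 15 were higher and 11 lower. Rescaling by cyclic loess gave 125 higher and 206 lower, a share of 37.8% higher against 27.3%. With the 2 arrays set aside after seeing the data left out, 69 were higher and 175 lower. The total was 71 without the array labelled 30 min replicate 2, 1125 without the array labelled 30 min replicate 1, 165 without nab2-td replicate 2 and 191 without nab2-td replicate 3. Without the array labelled 30 min replicate 2, the uracil permease gene FUR4 (1.54 with all arrays, 1.08 without it, adjusted p = 0.11), GAS2 (1.34, then 0.91, adjusted p = 0.16), DON1 (1.33, then 1.1, adjusted p = 0.065), ARP10 (-1.1, then -0.95, adjusted p = 0.067) and YSY6 (-1.1, then -0.69, adjusted p = 0.23) no longer passed. GAS2 also missed the threshold without nab2-td replicate 3 (adjusted p = 0.054), and YSY6 without nab2-td replicate 1 (0.057) or 2 (0.077). When the model held only the arrays of the groups compared, 1 gene passed. Array weights left 29, and leaving out the 3 arrays with a suffix left 186.

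Single genes of RNA processing differed in both directions at 30 min, and camera called no list of 3′-end formation, mRNA export or nuclear RNA decay. Of 25 genes for 3′-end formation, 2 rose (HRP1 and RNA14) and 2 fell relative to the wild type, over all genes and adjusted over the list alone (camera adjusted p = 0.06). Of 29 nuclear mRNA export genes, 3 were lower, among them SUS1 (-0.76, SE 0.12) and SEM1 (-0.53, SE 0.1), which both belong to the TREX-2 complex at the nuclear pore. Adjusted over the list alone, 2 export genes were higher and 4 lower (camera adjusted p = 0.82). AIR2, an RNA-binding subunit of the TRAMP complex of nuclear RNA decay, was lower by 0.98 (-0.98, SE 0.16, adjusted p = 0.0051), 1 of 2 called among 23 exosome, TRAMP and Nrd1 genes (3 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.62). Camera called 7 lists: ribosomal proteins (median -0.21, 2 of 128 lower, adjusted p = 1.9e-08), ribosome biogenesis (-0.21, 3 of 137 lower, 0.0097), Hsf1 chaperones (0.38, 0 of 25 called, 0.00056), Msn2/4 stress genes (0.31, 0 of 35, 0.0046), the proteasome (0.19, 1 of 33 lower, 0.00091), the TCA cycle (0.13, 1 of 16 higher, 0.0072) and G1/S genes (-0.34, 1 of 19 lower, 0.0064). Adjusted over the list alone, 2 ribosome biogenesis genes, 1 proteasome gene and 1 G1/S gene were lower, 1 TCA cycle gene was higher, and none passed in the other 3 lists. With an estimated correlation each had adjusted p = 0.95. Without the array labelled 30 min replicate 2 the medians were 0.01, 0.26, -0.04, -0.04, 0.02, 0.08 and -0.08, and of the 7 calls none was left in its direction. Without nab2-td replicate 2 the ribosome biogenesis median was -0.13 and its call was lost.

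At 75 min the strains differed in more than 1 gene in 3, in both directions. RRT5 was 5.04 log2 units higher in nab2-td (SE 0.22, limma adjusted p = 7e-08), SPO19 3.78 higher (SE 0.16, adjusted p = 4.9e-08) and REC102 2.11 higher (SE 0.19, adjusted p = 6.6e-06). The arginine synthesis gene ARG3 was higher by 1.87 (SE 0.19, adjusted p = 1.8e-05) and the ammonium permease gene MEP2 by 1.78 (SE 0.09, adjusted p = 2.2e-07). HRP1 was higher by 1.82 (SE 0.14, adjusted p = 2.6e-06). HOS2, a histone deacetylase subunit of the Set3 complex, stood at -2.46 (SE 0.18, adjusted p = 2e-06), THP3 at -2.18 (SE 0.18, adjusted p = 3.8e-06) and YOS1 at -1.93 (SE 0.1, adjusted p = 2.2e-07).

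Other genes with large rises were UBC11, a ubiquitin-conjugating enzyme (2.03), the aquaporin gene AQY2 (1.97, SE 0.4), BSC1 (1.96) and ARI1 (1.94). The wild-type mean of BSC1 (4.34) lay below the mark for dim genes, so its value is a lower bound and its rank is not exact. Among the genes with the lowest values were AAC1, a mitochondrial ADP/ATP carrier (-1.95), OST5, an oligosaccharyltransferase subunit (-1.92), SDH6 (-1.88) and VMA9, a subunit of the vacuolar proton pump (-1.84). TDA10 (-1.9), NCE101 (-1.89) and DYN2, a dynein light chain (-1.83), completed the 10. Each of these 20 genes kept its call when any 1 array was left out.

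In all, limma called 2114 of 5449 genes at 75 min (38.8%), 1007 higher and 1107 lower in nab2-td. By 2-fold or more, 76 were higher and 188 lower. As the arrays have nearly the same median, the balance of higher and lower does not show whether total transcript changed. Without the 2 wild-type arrays set aside after seeing the data, which are not part of this contrast but enter the shared spread, 1455 were higher and 1465 lower. The total was 1219 without the wild-type array labelled 75 min replicate 1 and 1290 without replicate 2. When only the arrays of the groups compared were in the model, 3453 genes passed, and with array weights 3673.

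**Figure D3:**
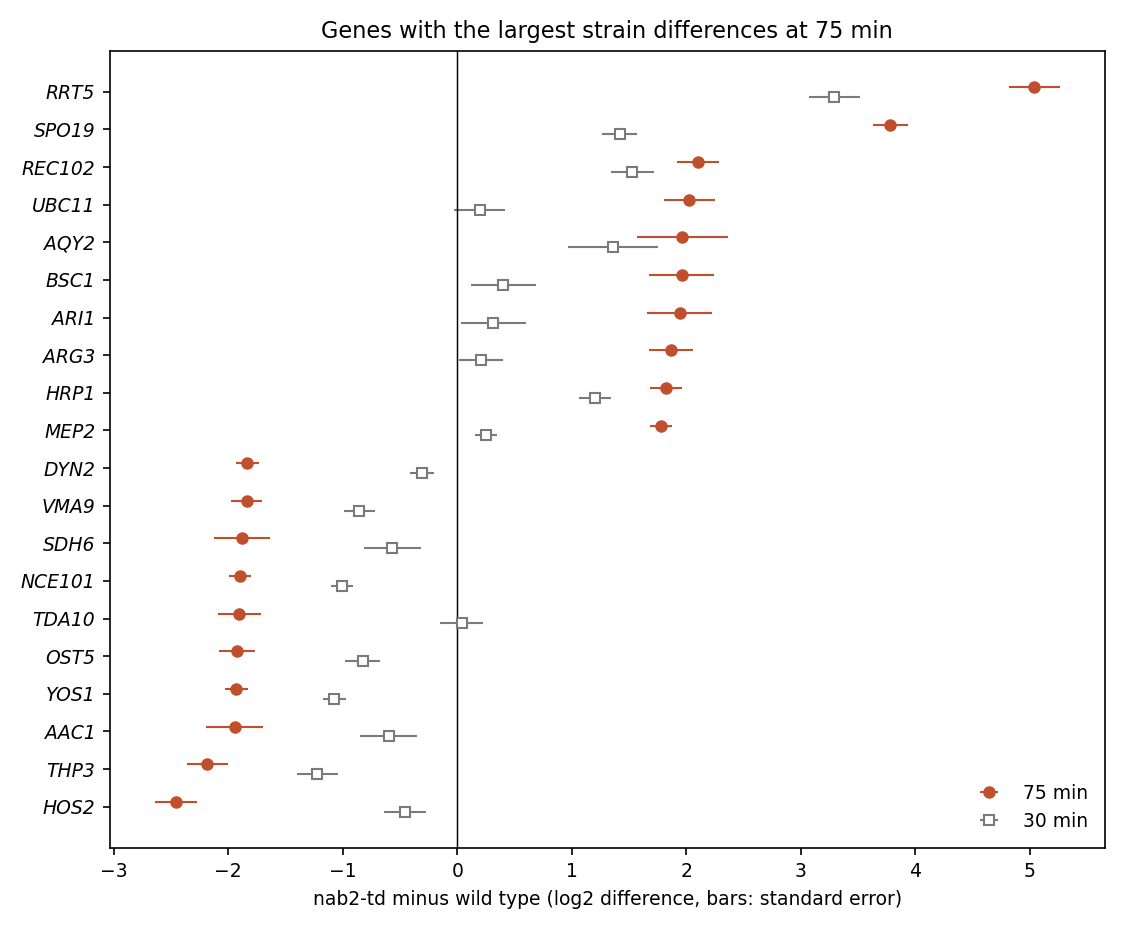
Difference between nab2-td and wild type (x axis, log2) for the 20 genes with the largest differences at 75 min that the naming rule took (y axis); filled circles are 75 min, open squares 30 min, and bars are standard errors from the model. RRT5 stands at 5.04 at 75 min and 3.3 at 30 min, HRP1 at 1.82 and 1.2, THP3 at -2.18 and -1.22.

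Amino acid synthesis genes driven by Gcn4 were higher in nab2-td at 75 min: 17 of 29 rose relative to the wild type, 1 was lower and 11 were not called (18 higher and 1 lower adjusted over the list alone). Their median was 0.44 log2 units (camera adjusted p = 1.6e-06; adjusted p = 0.98 with an estimated correlation). Besides ARG3, the lysine synthesis gene LYS1 was higher by 1.52 (SE 0.09) and the serine synthesis gene SER3 by 1.4 (SE 0.27). Of 32 genes of the respiratory chain and ATP synthase, 12 were lower, none was higher and 20 were not called, with 12 lower adjusted over the list alone. The median was -0.16 (camera adjusted p = 0.00094; adjusted p = 0.98 with an estimated correlation). ATP18 stood at -1.31 (SE 0.09) and ATP17 at -0.96 (SE 0.1), both ATP synthase subunits, and the cytochrome oxidase subunit genes COX6 and COX9 at -0.93 (SE 0.08) and -0.9 (SE 0.1). Of 137 ribosome biogenesis genes, 13 were higher, 4 lower and 120 not called, with 1 higher adjusted over the list alone. Their median was 0.29 (camera adjusted p = 0.019; adjusted p = 0.98 with an estimated correlation), and without the 2 arrays set aside 57 were higher and 6 lower. That list's call was lost without the wild-type array labelled 75 min replicate 1 (median 0.2) or without nab2-td replicate 1 (0.26).

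Genes of RNA processing and RNA polymerases changed in both directions at 75 min, and their lists were not called by camera. For 3′-end formation, 10 of 25 were higher and 5 lower, with 12 and 5 adjusted over the list alone (median 0.15, camera adjusted p = 0.079). RNA14 stood at 1.55 (SE 0.14) and REF2 at 1 (SE 0.08), while SYC1, a further subunit, stood at -1.34 (SE 0.12). For nuclear mRNA export, 8 of 29 were higher and 5 lower, the same numbers as when adjusted over the list alone (median 0.09, camera adjusted p = 0.49). SUS1 and SEM1 stood at -1.66 (SE 0.12) and -1.22 (SE 0.1), and HPR1 of the THO complex and the nucleoporin gene NUP42 at 0.96 (SE 0.16) and 0.81 (SE 0.16). Among 15 RNA polymerase I genes 5 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.17), with the initiation factor gene RRN3 at 1.52 (SE 0.09) and RRN7 at 0.78 (SE 0.09). Among 7 RNA polymerase II subunit genes, RPB11 (-0.91, SE 0.12) and RPB4 (-0.82, SE 0.08) belonged to 3 that were lower and 1 was higher, again also over the list alone (camera adjusted p = 0.33). Of 19 RNA polymerase III genes 5 were higher and 3 lower, with 7 and 3 adjusted over the list alone (camera adjusted p = 0.38), and 8 and 4 without the arrays set aside. Of 23 exosome, TRAMP and Nrd1 genes 6 were higher and 4 lower, as over the list alone (camera adjusted p = 0.33), with TRF5 at 0.68 (SE 0.14) and AIR2 at -0.87 (SE 0.16).

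Cytosolic ribosomal protein genes did not move as a group at 75 min: 16 of 128 were lower, none was higher and 112 were not called, with 8 lower adjusted over the list alone (median -0.07, camera adjusted p = 0.33). RPS22B stood at -1.42 (SE 0.27), RPS14B at -0.79 (SE 0.15) and RPL8A at -0.76 (SE 0.16). Of 33 proteasome genes 10 were higher and 3 lower, as over the list alone (median 0.21, camera adjusted p = 0.12), with RPN13 at -0.99 (SE 0.1) and PUP2 at -0.79 (SE 0.12). Of 35 Msn2/4 stress genes 7 were lower, with 4 adjusted over the list alone (median -0.24, camera adjusted p = 0.12), and of 25 Hsf1 chaperone genes 1 was lower and none passed over the list alone (median 0.01, camera adjusted p = 0.94). Leaving out the 2 arrays set aside gave 7 higher and 32 lower ribosomal protein genes, 17 higher and 5 lower proteasome genes, and 14 lower Msn2/4 genes with a camera call (adjusted p = 0.007).

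In the wild type, the arrays labelled 30 min did not differ from those labelled 0 min: limma called 0 of 5449 genes, and 16 had an unadjusted p under 0.05. The pairs of arrays with these labels crossed, as described above. Without the arrays labelled 0 min replicate 2 and 30 min replicate 2, 1 array was left on each side, whose spread was taken from the other groups, and 1314 genes were called, 635 higher and 679 lower. In that setting the membrane stress protein gene HSP30 stood at 5.28 log2 units (adjusted p = 0.00052), the small heat shock protein gene HSP26 at 3.37 (adjusted p = 0.00052) and the Hsp70 genes SSA4 and SSA3 at 3.24 (adjusted p = 1.9e-06) and 2.77 (adjusted p = 0.0017). With all arrays they stood at 0.37, 0.25, 0.02 and 0.11 (adjusted p = 1 each). In the same setting 93 of 128 ribosomal protein genes and 97 of 137 ribosome biogenesis genes were lower, 22 of 25 Hsf1 chaperone genes and 22 of 35 Msn2/4 stress genes were higher, 10 of 33 proteasome genes were higher and 19 of 25 translation factor genes were lower. With all arrays, camera called ribosome biogenesis (median 0.07, adjusted p = 2.5e-06), the respiratory chain (-0.06, 0.0012) and the proteasome (0.02, 0.017), with adjusted p = 0.98 with an estimated correlation in each. No member of these 3 lists passed over all genes or adjusted over the list alone. These 3 medians changed sign or lost the call with single arrays: ribosome biogenesis was -0.37 without the array labelled 0 min replicate 2 and -0.41 without that labelled 30 min replicate 2. The respiratory chain lost its call without the arrays labelled 0 min replicate 1 (-0.05) or 2 (-0.04) and turned without that labelled 30 min replicate 2 (0.02), and the proteasome turned without those labelled 0 min replicate 1 (-0.14) or 30 min replicate 1 (-0.16) and lost its call under quantile and cyclic loess scaling (0.02 in both).

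At 75 min, wild-type cells had more transcript of genes that build ribosomes than on the arrays labelled 0 min, and less of TCA cycle genes. INA1 was 3.47 log2 units higher (SE 0.25, limma adjusted p = 2.4e-05), the plasma membrane transporter gene AQR1 2.95 (SE 0.22, adjusted p = 2.4e-05), the riboflavin transporter gene MCH5 2.49 (SE 0.43, adjusted p = 0.003) and the adenine deaminase gene AAH1 2.47 (SE 0.33, adjusted p = 0.00061). ECI1, a peroxisomal enzyme of fatty acid breakdown, stood at -1.65 (SE 0.27, adjusted p = 0.0021) and SFC1, a mitochondrial succinate carrier, at -1.64 (SE 0.27, adjusted p = 0.0025). In all 1101 genes were called, 539 higher and 562 lower, and by 2-fold or more 137 and 54. Without the 2 arrays set aside after seeing the data, 762 were higher and 623 lower. The total was 424 without the array labelled 75 min replicate 1 and 263 without replicate 2. When only the arrays of the groups compared were in the model, limma called 0. Array weights gave 401, and leaving out the 3 arrays with a suffix 2117. The peptide transporter gene PTR2 stood at 3.5 (adjusted p = 0.022) and at 1.78 without the array labelled 0 min replicate 1 (adjusted p = 0.099). PTR2, DMC1 (-1.71) and SUR7 (-1.62) missed the threshold without either array labelled 75 min (adjusted p = 0.099 and 0.12, 0.059 and 0.074, 0.056 and 0.074). The malate synthase gene MLS1 (-1.77) missed it without the array labelled 75 min replicate 1 (0.13) or 0 min replicate 1 (0.055).

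Of 137 ribosome biogenesis genes, 71 rose in the wild type by 75 min, none fell and 66 were not called, with 115 higher adjusted over the list alone (median 0.96, camera adjusted p = 3.3e-27; adjusted p = 0.44 with an estimated correlation). DHR2, an RNA helicase of small subunit assembly, stood at 2.06 (SE 0.36) and REX4 at 1.62 (SE 0.29), and without the 2 arrays set aside the list's median was 0.54. RNA polymerase I genes rose in 6 of 15 (9 over the list alone, median 0.55, camera adjusted p = 0.00089; adjusted p = 0.5 with an estimated correlation), with RRN11 at 1.32 (SE 0.23). RNA polymerase III genes rose in 7 of 19 and fell in 1 (9 and 1 over the list alone, median 0.39, camera adjusted p = 0.00064; adjusted p = 0.26 with an estimated correlation), with RPC25 at 1.09 (SE 0.1) and RPC17 at 0.91 (SE 0.14). Its median was 0.21 without the arrays set aside. Exosome, TRAMP and Nrd1 genes rose in 10 of 23 (14 over the list alone, median 0.37, camera adjusted p = 2.2e-06; adjusted p = 0.31 with an estimated correlation), with RRP4 at 0.84 (SE 0.08). Genes of the unfolded protein response rose in 8 of 14 (8 over the list alone, median 0.36, camera adjusted p = 0.00064; adjusted p = 0.26 with an estimated correlation), with ERO1 at 1.43 (SE 0.27), JEM1 at 1.12 (SE 0.14) and SCJ1 at 0.9 (SE 0.11). Of 16 TCA cycle genes 10 fell (14 over the list alone, median -0.34, camera adjusted p = 3.2e-06; adjusted p = 0.26 with an estimated correlation), with IDH1 at -0.45 (SE 0.08) and FUM1 at -0.43 (SE 0.08). Each of these 6 lists kept its call when any 1 array was left out.

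Further lists moved in the wild type by 75 min. G2/M genes fell in 5 of 12 (8 over the list alone, median -0.5, camera adjusted p = 7.9e-05; adjusted p = 0.44 with an estimated correlation), with IQG1 at -0.58 (SE 0.09), and 12 were lower without the arrays set aside. Iron regulon genes fell in 7 of 18 and rose in 1 (8 and 1 over the list alone, median -0.34, camera adjusted p = 0.0089; adjusted p = 0.26 with an estimated correlation), with the heme oxygenase gene HMX1 at -1.29 (SE 0.2), and this call was lost without the array labelled 0 min replicate 1 (median -0.34). Respiratory genes fell in 3 of 32 (0 over the list alone, median -0.14, camera adjusted p = 0.00089; adjusted p = 0.67 with an estimated correlation). G1/S genes rose in 4 of 19 (8 over the list alone, median 0.44, camera adjusted p = 0.00071; adjusted p = 0.67 with an estimated correlation), a call lost without the array labelled 0 min replicate 2 (0.22). Ribosomal protein genes rose in 3 of 128 (1 over the list alone, median 0.23, camera adjusted p = 6.5e-07) and translation factor genes rose in 1 of 25 and fell in 1 (0 and 1 over the list alone, median 0.28, camera adjusted p = 0.031), each with adjusted p = 0.72 with an estimated correlation. Both of these medians were 0 without the array labelled 0 min replicate 2, and translation factors also lost the call without the array labelled 75 min replicate 2 (0.23). The a-cell genes rose in 4 of 7 and fell in 1 (the same over the list alone, median 0.44, camera adjusted p = 0.039; adjusted p = 0.44 with an estimated correlation). That call was lost without the arrays labelled 0 min replicate 1 (0.35), 75 min replicate 1 (0.43), or 30 min replicate 1 or 2 (0.44 in both), and the median was 0.73 without the arrays set aside. Hsf1 chaperone genes were not called with all arrays (0 of 25, also over the list alone; median 0.32, camera adjusted p = 0.064). When the 2 arrays set aside were left out, 17 were higher (median 0.76, camera adjusted p = 5.2e-13). Proteasome genes went from 0 of 33 (median 0.06, camera adjusted p = 0.27) to 7 higher (0.2, 0.0011) in that setting. Msn2/4 stress genes turned there from -0.13 (0.064) to 0.28, with 14 higher and 3 lower (0.036). The GAL (0.31, 0.0064), copper-regulated (0.43, 0.0029) and Gcn4 lists (-0.27, 0.0013) were called there as well.

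In nab2-td at 30 min, heat shock chaperone and proteasome genes rose, and ribosomal protein genes fell. The chaperone genes SSA3, HSP26 and SSA4 rose by 3.68 (SE 0.67, limma adjusted p = 0.0021), 3.43 (SE 0.77, adjusted p = 0.0057) and 3.13 log2 units (SE 0.77, adjusted p = 0.0087). HSP26 reached 14.38, near the highest value of the arrays, so its rise can be larger than measured. RRT5 rose by 3.37 (SE 0.2, adjusted p = 5.9e-06) and PTR2 by 3.16 (SE 0.76, adjusted p = 0.0078). PHO11, an acid phosphatase gene read by a probe set shared with close copies, stood at -3.13 (SE 0.69, adjusted p = 0.0053), and the S-adenosylmethionine synthetase gene SAM1 at -3.08 (SE 0.71, adjusted p = 0.0065). PHM6 (-2.9), SEO1 (-2.18) and the transporter gene QDR2 (-2.01) were the other large falls. HSP30 stood at 3.78 (SE 1.21, adjusted p = 0.027), and its call was lost without nab2-td 0 min replicate 1 (3.99, adjusted p = 0.056), 2 (4.04, 0.05) or 3 (3.32, 0.083), or 30 min replicate 2 (3.69, 0.07) or 3 (3.71, 0.071). In all 2263 genes were called, 1050 higher and 1213 lower, and by 2-fold or more 110 and 98. Without the 2 wild-type arrays set aside, which enter this contrast through the shared spread alone, 1460 were higher and 1601 lower. With array weights the total was 3587.

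Of 128 ribosomal protein genes, 98 fell in nab2-td by 30 min, none rose and 30 were not called, with 113 lower adjusted over the list alone (median -0.44, camera adjusted p = 1.4e-15; adjusted p = 0.69 with an estimated correlation, as for each list called in this comparison). RPS22B stood at -1.29 (SE 0.24) and RPL23A at -0.93 (SE 0.2). Hsf1 chaperone genes rose in 21 of 25 (22 over the list alone, median 0.9, camera adjusted p = 1.7e-08). Proteasome genes rose in 31 of 33 and fell in 1, as over the list alone (median 0.5, camera adjusted p = 1.5e-10), with PRE4 at 0.66 (SE 0.11) and PRE7 at 0.64 (SE 0.12). Msn2/4 stress genes rose in 17 of 35 (23 higher and 1 lower over the list alone, median 0.6, camera adjusted p = 4.1e-05), with TKL2 at 1.99 (SE 0.49) and NQM1 at 1.78 (SE 0.38). Translation factor genes fell in 9 of 25 (12 over the list alone, median -0.33, camera adjusted p = 0.0014), with TIF11 at -0.74 (SE 0.15). G1/S genes fell in 11 of 19 (12 over the list alone, median -0.44, camera adjusted p = 0.0073), with the thymidylate synthase gene CDC21 at -1.04 (SE 0.21). G2/M genes fell in 7 of 12 (9 over the list alone, median -0.37, camera adjusted p = 0.0081), with SWI5 at -0.85 (SE 0.19). Of 25 genes for 3′-end formation 8 rose and 4 fell, as over the list alone (median 0.15, camera adjusted p = 0.048), with HRP1 at 1.61 (SE 0.13), RNA14 at 1.1 (SE 0.12) and SYC1 at -0.65 (SE 0.1). Of 32 respiratory genes 11 fell, as over the list alone (median -0.11, camera adjusted p = 0.044). When the wild-type arrays set aside were left out, 29 Msn2/4 genes were higher and 1 lower, and 21 translation factor genes were lower. Ribosome biogenesis was then called too (9 higher and 52 lower, median -0.2, adjusted p = 0.0093; 0.15 with all arrays), as were GAL genes (0.33, 0.03) and glycolysis (-0.11, 0.033).

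The calls for 3′-end formation and respiration rested on single arrays and on the scaling, and both were lost when the wild-type arrays set aside were left out (adjusted p = 0.079 in both). The 3′-end call was lost under median centring (0.14) and cyclic loess (0.16), and without the wild-type arrays labelled 0 min replicate 1 or 2 or 75 min replicate 1 or 2, or nab2-td 0 min replicate 1 (median 0.15 in each), or nab2-td 30 min replicate 3 (0.12). The respiratory call was lost under quantile (-0.07) and cyclic loess (-0.09) scaling of the tested genes, and without the wild-type arrays labelled 0 min replicate 1 or 2 (-0.11 in both), nab2-td 0 min replicate 1 (-0.08) or 2 (-0.1), or nab2-td 30 min replicate 3 (-0.06).

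By 75 min, ribosome biogenesis genes had risen in nab2-td and genes of mitochondrial respiration had fallen. RRT5 rose by 5.82 log2 units (SE 0.2, limma adjusted p = 4e-09), SPO19 by 5.06 (SE 0.14, adjusted p = 8.9e-10), PTR2 by 5.02 (SE 0.76, adjusted p = 0.00011), AQR1 by 4.5 (SE 0.18, adjusted p = 7.7e-09) and HSP30 by 4.46 (SE 1.21, adjusted p = 0.0066). The value of SPO19 is a lower bound, since its mean at 0 min (3.34) was that of a dim gene. DMC1 stood at -2.91 (SE 0.31, adjusted p = 7.7e-06), CMC4 at -2.8 (SE 0.1, adjusted p = 4e-09), the citrate synthase gene CIT3 at -2.78 (SE 0.19, adjusted p = 2.9e-07), AGP2 at -2.69 (SE 0.2, adjusted p = 5.7e-07) and COX17, a copper chaperone of cytochrome oxidase, at -2.58 (SE 0.16, adjusted p = 1.5e-07). In all 3404 genes were called, 1680 higher and 1724 lower, and by 2-fold or more 464 and 404. The counts were 1972 and 1968 without the 2 wild-type arrays set aside.

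Ribosome biogenesis genes rose in 119 of 137 in nab2-td by 75 min, none fell and 18 were not called, with 120 higher adjusted over the list alone (median 1.17, camera adjusted p = 4.5e-15; adjusted p = 0.53 with an estimated correlation, as for each list called here except where given). The RNA helicase genes DBP2, DHR2 and FAL1 stood at 4.11 (SE 0.65), 3.16 (SE 0.3) and 2.38 (SE 0.27), and UTP5 at 2.25 (SE 0.28). RNA polymerase I genes rose in 11 of 15 and fell in 1 (as over the list alone, median 0.71, camera adjusted p = 0.0059), with RRN11 at 2.45 (SE 0.19) and RRN3 at 1.75 (SE 0.08). RNA polymerase III genes rose in 13 of 19 and fell in 1 (as over the list alone, median 0.33, camera adjusted p = 0.005), with RPC17 at 1.41 (SE 0.11) and RPC25 at 1.27 (SE 0.08). Exosome, TRAMP and Nrd1 genes rose in 17 of 23 and fell in 1 (as over the list alone, median 0.47, camera adjusted p = 0.00048), with TRF5 at 1.67 (SE 0.13) and RRP4 at 1.62 (SE 0.07). Respiratory genes fell in 27 of 32, none rose (28 lower over the list alone, median -0.47, camera adjusted p = 9.1e-07), with ATP18 at -1.47 (SE 0.08), ATP19 at -1.12 (SE 0.09) and COX9 at -1.07 (SE 0.09). TCA cycle genes fell in 10 of 16 (as over the list alone, median -0.34, camera adjusted p = 0.024), a call that ended under quantile (-0.31) and cyclic loess (-0.27) scaling. G2/M genes were called only when the wild-type arrays set aside were left out (1 higher and 8 lower, median -0.52, adjusted p = 0.039; 0.069 with all arrays).

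Protein quality control genes stayed raised in nab2-td at 75 min. Proteasome genes were higher than at 0 min in 28 of 33 and lower in 2 (29 and 2 over the list alone, median 0.51, camera adjusted p = 3.8e-05; adjusted p = 0.6 with an estimated correlation), with PRE4 at 0.85 (SE 0.11) and RPN13 at -0.87 (SE 0.09). Hsf1 chaperone genes were higher in 18 of 25 and lower in 1 (20 and 1 over the list alone, median 0.92, camera adjusted p = 0.0035; adjusted p = 0.66 with an estimated correlation), with HSP26, again near the highest value, at 3.39 (SE 0.77) and SSA3 at 3.14 (SE 0.67). This response of the Hsf1 list was not shown to differ from the wild type's (median difference 0.57, camera adjusted p = 0.053; 0.09 and 0.83 when the 2 arrays set aside were left out). Gcn4 amino acid genes rose in 14 of 29 and fell in 5 (15 and 5 over the list alone, median 0.41, camera adjusted p = 0.0099; adjusted p = 0.53 with an estimated correlation). LYS20 stood at 2.16 (SE 0.19), the asparagine synthetase gene ASN1 at 2.08 (SE 0.15) and HOM3 at 1.89 (SE 0.1), while SNO1, a vitamin B6 gene of the same list, stood at -2.4 (SE 0.26). Core histone genes rose in 6 of 7 (as over the list alone, median 0.33, camera adjusted p = 0.024; adjusted p = 0.53 with an estimated correlation), with HTA1 at 0.65 (SE 0.08) and HHT2 at 0.53 (SE 0.09). Iron regulon genes fell in 11 of 18 and rose in 2 (12 and 2 over the list alone, median -0.49, camera adjusted p = 0.046; adjusted p = 0.53 with an estimated correlation), with the multicopper oxidase gene FET3 at -1.71 (SE 0.35), and this call was lost under median centring (-0.52), without dim genes (-0.39), and without nab2-td 0 min replicate 1 (-0.6) or 75 min replicate 3 (-0.47).

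**Figure D4:**
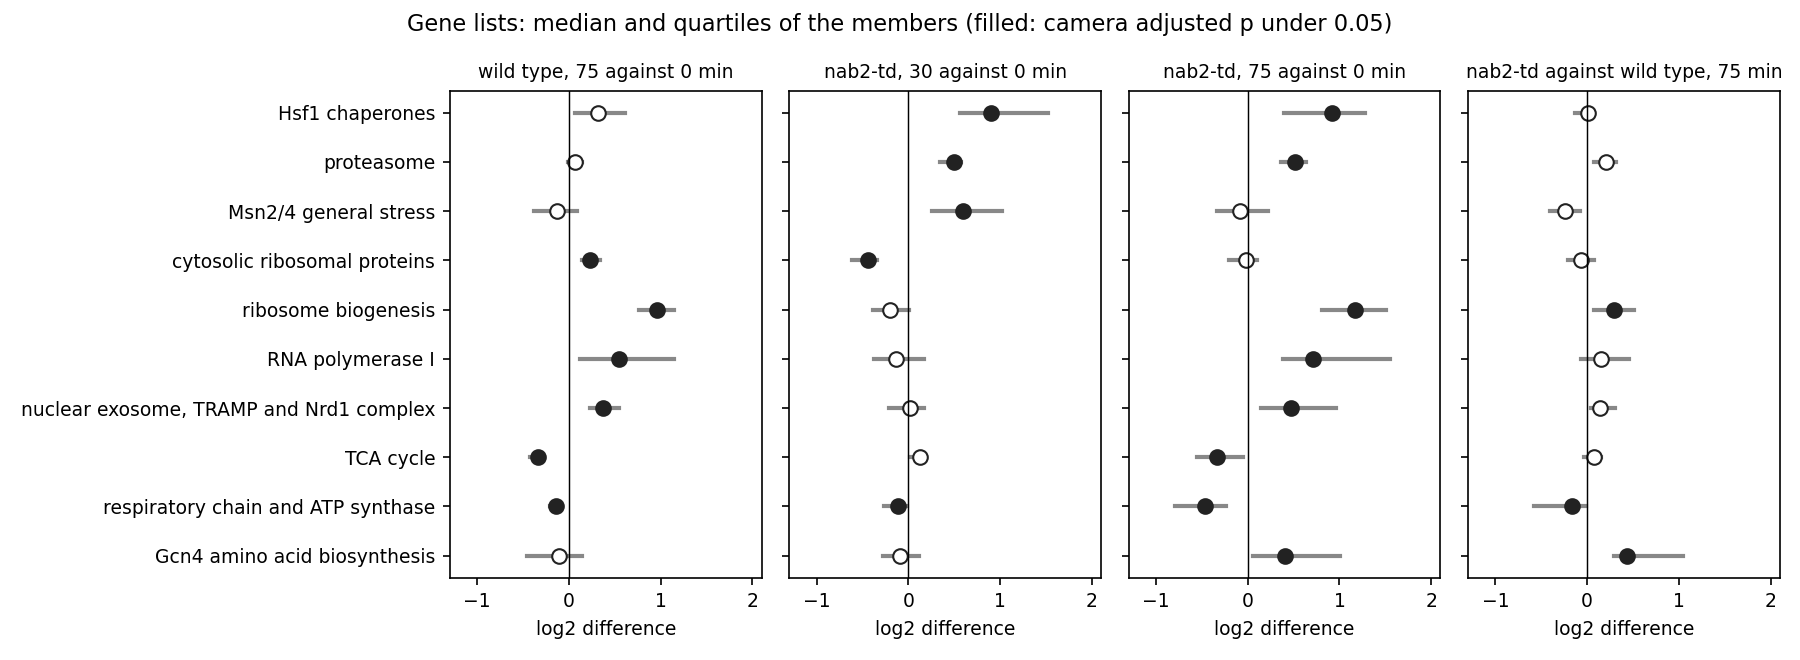
Median log2 difference of the members of 10 gene lists (x axis; bars are the quartiles of the members) in 4 comparisons (panels); filled circles have a camera adjusted p under 0.05 with the preset correlation of 0.01, and none of them does with an estimated correlation. Ribosome biogenesis stands at 0.96 in the wild type and 1.17 in nab2-td at 75 against 0 min, ribosomal proteins at -0.44 in nab2-td at 30 min, and Gcn4 genes at 0.44 between the strains at 75 min.

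The difference between the strains in their response from 0 to 75 min was tested as an interaction. RRT5 (5.35 log2 units, SE 0.31, limma adjusted p = 1.9e-06), SPO19 (4.22, SE 0.22, adjusted p = 7.7e-07) and REC102 (2.8, SE 0.26, adjusted p = 3.8e-05) changed more in nab2-td, as did AQY2 (2.36, SE 0.56, adjusted p = 0.0093). SPO19 was dim in both strains at 0 min (3.77 in the wild type), so the size of its difference is not exact. COX17 (-2.33, SE 0.26, adjusted p = 8.3e-05), OST5 (-2.2, SE 0.22, adjusted p = 4.6e-05), HOS2 (-2.15, SE 0.26, adjusted p = 0.00015), POP8, a subunit of RNase P and RNase MRP (-2.03, SE 0.28, adjusted p = 0.00036), and ZNF1 (-1.97, SE 0.46, adjusted p = 0.0083) changed the other way. In all 1520 genes had different responses, 720 in the positive and 800 in the negative direction, and by 2-fold or more 105 and 203. Without the 2 wild-type arrays set aside after seeing the data the counts were 962 and 1043. The total was 893 without the array labelled 75 min replicate 1 and 972 without replicate 2. PCK1, of gluconeogenesis (2.59, SE 0.8, adjusted p = 0.031), missed the threshold without wild-type 0 min replicate 1 (0.053) or 2 (0.067), wild-type 75 min replicate 1 (0.14), nab2-td 0 min replicate 1 (0.053), or nab2-td 75 min replicate 1 (0.062), 2 (0.056) or 3 (0.052).

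Gcn4 amino acid genes responded more positively in nab2-td by 75 min in 12 of 29 and more negatively in 1 (14 and 1 over the list alone, median 0.49, camera adjusted p = 3.3e-05; adjusted p = 0.91 with an estimated correlation, as for the next 3 lists). ARG3 stood at 1.82 (SE 0.27), HOM3 at 1.61 (SE 0.17) and LYS1 at 1.57 (SE 0.12). Without the arrays set aside 20 responded more positively. Proteasome genes did so in 15 of 33, with 1 the other way (22 and 2 over the list alone, median 0.49, camera adjusted p = 5.6e-05), and RPN3 (0.85, SE 0.22) and PRE4 (0.72, SE 0.18) were among them. The list's median was 0.32 without the arrays set aside. Without the array labelled 0 min replicate 2, RPN3 (0.7, adjusted p = 0.05) and PRE4 (0.55, adjusted p = 0.05) no longer passed. Respiratory genes responded more negatively in 11 of 32 (13 over the list alone, median -0.24, camera adjusted p = 5.6e-05), with ATP18 at -1.39 (SE 0.13) and COX6 at -0.93 (SE 0.11). Ribosomal protein genes responded more negatively in 14 of 128 (8 over the list alone, median -0.26, camera adjusted p = 6.5e-05), with RPS22B at -1.86 (SE 0.38) and RPL8A at -1.05 (SE 0.22), and this list's call was lost without the array labelled 0 min replicate 2 (-0.03). When the 2 arrays set aside were left out, 80 of 137 ribosome biogenesis genes responded more positively and 1 more negatively (median 0.69, camera adjusted p = 4.8e-13; 0.27 and 0.088 with all arrays). In that setting 16 of 35 Msn2/4 genes responded more negatively (median -0.42, camera adjusted p = 0.0014; 0.05 and 0.89 with all arrays). RNA polymerase I (0.39, 0.026) and exosome, TRAMP and Nrd1 genes (0.28, 0.024) were called there as well.

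For the response from 0 to 30 min, 263 genes had different responses in the strains, 96 in the positive and 167 in the negative direction, and by 2-fold or more 29 and 29. RRT5 (3.61, SE 0.31, limma adjusted p = 0.00047) and REC102 (2.23, SE 0.26, adjusted p = 0.0014) changed more in nab2-td. Without the 2 wild-type arrays set aside after seeing the data, 27 were positive and 33 negative. Array weights ended every call (0 genes), a model with only the groups compared left 25, and leaving out the 3 arrays with a suffix gave 821. The total changed by more than 1.5 times with 12 of the 15 arrays. It was 1650 and 42 without the wild-type arrays labelled 0 min replicates 1 and 2, 1666 and 46 without those labelled 30 min replicates 1 and 2, and 121 without either labelled 75 min. It was 133 and 113 without nab2-td 0 min replicates 1 and 2, 112 and 139 without nab2-td 30 min replicates 2 and 3, and 157 and 148 without nab2-td 75 min replicates 1 and 3. Camera called 8 lists: Hsf1 chaperones (median 0.86, adjusted p = 1.1e-07), Msn2/4 stress genes (0.61, 0.00012), the proteasome (0.46, 4.2e-09), ribosomal proteins (-0.43, 9.7e-15), ribosome biogenesis (-0.26, 0.035), translation factors (-0.36, 0.0018), G1/S genes (-0.48, 0.0032) and G2/M genes (-0.44, 0.0031). Over all genes, 1 proteasome and 1 ribosome biogenesis gene passed in the positive direction, and 2 ribosomal protein genes in the negative direction. Adjusted over the list alone, 14 Hsf1 chaperone genes, 20 proteasome genes and 1 ribosome biogenesis gene passed in the positive direction, and 1 proteasome gene and 5 G2/M genes in the negative direction. With an estimated correlation the adjusted p was 0.73 for each except ribosome biogenesis (adjusted p = 0.92 with an estimated correlation). Without the arrays labelled 0 min replicate 2 or 30 min replicate 2, the medians were 0.18 and 0.2 for Msn2/4 genes, -0.11 and -0.1 for translation factors, -0.22 and -0.23 for G1/S genes and -0.29 and -0.31 for G2/M genes, no longer called, and 0.14 and 0.18 for ribosome biogenesis. With both left out they were 0.02 for Hsf1 chaperones (adjusted p = 0.89), -0.18 for Msn2/4 genes (0.032), 0.14 for the proteasome (0.032), 0.03 for ribosomal proteins (0.36), 0.61 for ribosome biogenesis (5.2e-28), 0.15 for translation factors (0.032), 0.06 for G1/S genes (0.45) and -0.1 for G2/M genes (0.79). Of the 8 calls only the proteasome's was left in its direction. Lists not called with all arrays shifted there too: RNA polymerase I (median 0.36), Gcn4 amino acid genes (0.22), exosome, TRAMP and Nrd1 genes (0.14), RNA polymerase III (0.11) and respiratory genes (-0.09). That setting has 1 wild-type array at each of these times. The ribosome biogenesis call was also lost with a replicate block (-0.26) and without nab2-td 0 min replicate 1 (-0.22) or 3 (-0.23) or 30 min replicate 2 (-0.18).

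Across genes, the responses of the strains from 0 to 75 min were correlated (Pearson r = 0.69, Spearman rho = 0.63 over 5449 genes, which are not independent replicates), and 71.8% of genes had the same sign. The orthogonal slope of nab2-td on wild type was 2.08, and r was 0.55 without the wild-type array labelled 0 min replicate 1. For 0 to 30 min the values were r = -0.01 and rho = -0.02, with 49% of the same sign, where the wild-type arrays carry the crossed labels. These were 2 relations of 1 family, given as descriptions without a test. Of the 90 genes higher in nab2-td at 30 min, 83 were also among the 1007 higher at 75 min, where independent lists would share 16.6. Of the 240 lower at 30 min, 210 were among the 1107 lower at 75 min, where 48.8 would be shared. Another 3 genes higher at 30 min were lower at 75 min (AUA1, ARE2 and YDL086W), and 2 went from lower to higher (PLM2 and NUD1), all named after their values were seen. The sum of shared genes in the same direction was 71 without the wild-type array labelled 30 min replicate 2, 547 without that labelled 30 min replicate 1, 155 without nab2-td 30 min replicate 2 and 179 without replicate 3.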

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

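All tests of the crossed wild-type arrays, and those of the genes at least 2-fold higher, were chosen after the result was seen; the other tests in this part were chosen before.

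The strains' responses from 0 to 75 min differed by a test of the difference itself for 1520 genes. Among the named genes the difference was 5.35 log2 units for RRT5, 4.22 for SPO19, 2.8 for REC102, 2.59 for PCK1, 2.36 for AQY2, 1.82 for ARG3, 1.61 for HOM3, 1.57 for LYS1, 0.85 for RPN3 and 0.72 for PRE4. It was -2.33 for COX17, -2.2 for OST5, -2.15 for HOS2, -2.03 for POP8, -1.97 for ZNF1, -1.86 for RPS22B, -1.39 for ATP18, -1.05 for RPL8A and -0.93 for COX6. The count of 1520 and the calls of PCK1, RPN3 and PRE4 changed when single arrays were left out, as given above. The lists with a different response had medians of 0.49 for Gcn4 amino acid genes, 0.49 for the proteasome, -0.26 for ribosomal proteins and -0.24 for respiratory genes. Each had adjusted p = 0.91 with an estimated correlation, and the call for ribosomal proteins was lost without the array labelled 0 min replicate 2 (-0.03).

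The responses from 0 to 30 min differed for 263 genes, among them RRT5 (3.61) and REC102 (2.23). Array weights left 0 genes, and leaving out single arrays changed the count, as given above. The list medians of the difference were 0.86 for Hsf1 chaperones, 0.61 for Msn2/4 stress genes, 0.46 for the proteasome, -0.26 for ribosome biogenesis, -0.36 for translation factors, -0.43 for ribosomal proteins, -0.44 for G2/M genes and -0.48 for G1/S genes. Each had adjusted p = 0.73 with an estimated correlation, except ribosome biogenesis (0.92), and with the 2 wild-type arrays set aside left out the medians were 0.02 for Hsf1 chaperones, -0.18 for Msn2/4 genes, 0.14 for the proteasome, 0.61 for ribosome biogenesis and 0.03 for ribosomal proteins. Among 3517 probe sets without a gene symbol, which no comparison used, 58 passed limma's test between the strains at 75 min, 17 higher and 41 lower in nab2-td. Of the 1747 probe sets whose gene is not in the S. cerevisiae table, limma called 0 in that contrast, with 80 at unadjusted p under 0.05.

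The wild-type arrays labelled 0 and 30 min paired across their labels: on the axis of the nab2-td response to 30 min, the arrays of a label lay at least 0.71 apart, which is what an exchange of the labels of 1 array of each group would give. A day shared by arrays of the same number, as the cause, is argued against by the correlation of -0.93 between their deviations. RNA quality stays open: the mean 3′ minus 5′ difference of 6 control genes set the look-alike pairs 0.035 apart, while arrays within a pair differed by up to 0.08, but the ribosomal RNA signal set them 0.65 apart, while arrays within a pair differed by up to 0.49. A wild type without a response by 30 min, as the cause, would leave all of these arrays near the nab2-td mean at 0 min. The positions of 0.83 and 0.82, on 1 array of each label, argue against it. Whether the wild type had responded by 30 min cannot be read from arrays whose labels cross. An exchange of labels may account for the pattern, as a hypothesis found and tested on the same arrays, and the files name no exchange. On the axis, the arrays that lay against their label were 0 min replicate 2 (0.82) and 30 min replicate 2 (0.1). The other look-alike array of the latter, labelled 0 min replicate 1, shares with it a suffix in the description. What the suffix stands for was not tested.

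Short genes were lower in nab2-td than in the wild type at 75 min: across 5446 genes the Spearman correlation of gene length with the difference was 0.244, and of the 1096 genes spanning at most 660 bases 458 were lower and 73 higher. Weak signals near background are argued against, since among the 2723 brighter genes the correlation was 0.291. Interrupted genes as the whole cause are argued against by the 5282 genes whose span is a multiple of 3, where the correlation was 0.226. RNA quality stays open: the 3′ minus 5′ difference was smaller in all 3 nab2-td arrays (0.98, 0.94 and 1.03) than in both wild-type arrays (1.07 and 1.05), with -0.13 between the lowest and the highest. An effect of Nab2 loss on short transcripts may remain, as a hypothesis, and how the probe sets of short genes are placed was not tested.

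Several weakly expressed genes that rose in nab2-td at 75 min lie behind a gene on the same strand, such as RRT5 behind RPL29 and SPO19 behind RPL5. Among 1138 genes in the lowest 25% of the wild-type level, the 554 behind a same-strand neighbour had a median difference 0.04 above that of the 584 behind a divergent one (one-sided permutation p = 0.084), which leaves a floor effect of weak signals open there. The correlation with the neighbour's level differed by 0.04 (permutation p = 0.54, two-sided), and so small a difference keeps transcripts running on from the neighbour open. The next tests cover genes that include RRT5 and SPO19, which prompted them, so their p values are no independent evidence. Of the 62 genes at least 2-fold higher with a measured neighbour, 74.2% lay behind a same-strand gene. The share was 47.4% for genes of the same level (one-sided permutation p = 1e-05, the smallest possible). A floor effect stays open for these genes, some of which adjoin each other. Their neighbours' median level was 0.75 log2 units higher than for other genes so placed (one-sided permutation p = 0.005), a comparison of signals across different probe sets, and read-through from the neighbour stays open for these genes, as a hypothesis.

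For the counts of genes that changed in nab2-td, the 10 splits of the 6 arrays are too few for a share under 0.05. The real value was 2263 at 30 min and 3404 at 75 min, given by 1 split in each case, and the highest of the other splits was 0 for both by limma.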

How the results depend on the processing

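The number of arrays, 2 or 3 per group, limits the precision of every count. The settings that left out the arrays labelled 0 min replicate 2 and 30 min replicate 2, or crossed the replicate numbers, were chosen after seeing the data. The arrays with a suffix include those labelled 0 min replicate 1 and 30 min replicate 2. Leaving them out left 1 wild-type array at each of these times. The trended and robust variance model, all probe sets, the dim-gene filter and the 3 scalings kept every count of called genes within 1.5 times. Fitting only the groups compared gave 0 genes between the strains at 0 min, 1 at 30 min and 3453 at 75 min, 0 for the wild type at 75 min, 25 for the interaction at 30 min, and 3 of 6 construct calls. With a replicate block the strain difference counted 86 genes at 0 min and 199 at 30 min, and the interaction at 30 min 159. Deviations of same-numbered arrays correlated at 0.09 to 0.38 within nab2-td and at 0.16 to 0.41 between nab2-td and the wild type labelled 0 min, but at -0.46 to -0.1 between nab2-td and the later wild-type arrays, so 16 of 33 lay above 0.1 and a pairing by number was left open. In 18 of 18 cases a nab2-td array correlated best with its own number in another nab2-td group, a hint from the data, not the design. A block with the numbers of the 30 min wild-type arrays exchanged gave 254 genes at 0 min and 619 for the interaction at 30 min. Array weights gave 29 and 3673 genes for the strain difference at 30 and 75 min, 401 for the wild type at 75 min, 3587 for nab2-td at 30 min and 0 for the interaction at 30 min. A minimum log2 difference of 1, which takes fewer genes by construction, left 26 and 264 genes between the strains at 30 and 75 min, 191 for the wild type at 75 min, 208 and 868 for nab2-td at 30 and 75 min, and 58 and 308 for the interactions. Without the 3 arrays with a suffix there were 1836 and 186 genes between the strains at 0 and 30 min, 2117 for the wild type at 75 min and 821 for the interaction at 30 min. Without the 2 wild-type arrays set aside there were 1314 genes for the wild type at 30 min and 60 for the interaction at 30 min. Camera called 67 list tests with the preset correlation, 0 with an estimated one, and fry, whose hypothesis differs, 47. The cause was not tested for any of these but the minimum difference.

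Leaving out 1 array at a time gave 2 to 201 genes between the strains at 0 min, 71 to 1125 at 30 min and 1219 to 2343 at 75 min. For the wild type it gave 0 to 0 genes at 30 min and 263 to 1412 at 75 min, and for nab2-td 1518 to 2612 and 2998 to 3597. The interactions ranged from 42 to 1666 at 30 min and from 893 to 1783 at 75 min, the correlation of the responses from 0.55 to 0.72, and the shared strain differences from 71 to 547. The construct calls stayed at 6 to 6 and the list calls ranged from 65 to 94. The cause was not tested.

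Of 192 gene results named in the text, 0 that were called reversed and 129 kept their side of the threshold in each setting run for single genes, which did not include the minimum log2 difference of 1, the crossed block or leaving out all 4 wild-type arrays labelled 0 and 30 min. Uncalled values changed sign in 14 cases, among them UBR1 (-0.15), GAL1 (-0.02) and CUP1-1 (-0.05) between the strains at 30 min without the arrays set aside. List medians reversed in 37 cases, and the cause was not tested. Settings that leave the same arrays in a contrast give the same median, so these cases repeat each other in part. Between the strains at 30 min, ribosomal proteins had a median of 0.01, ribosome biogenesis 0.26, Hsf1 chaperones -0.04 and Msn2/4 genes -0.04 in each of 3 settings: without the arrays with a suffix, without the array labelled 30 min replicate 2, and without the arrays set aside. All 3 leave the array labelled 30 min replicate 1 as the only wild-type array there, so they are 1 result. Between the strains at 0 min, without the array labelled 0 min replicate 2 or both set aside, ribosomal proteins had -0.01, Msn2/4 genes 0.12 and translation factors -0.02, and in the wild type at 75 min ribosomal proteins had 0 and translation factors 0. In the wild type at 30 min, ribosome biogenesis had -0.37 without the array labelled 0 min replicate 2, -0.41 without that labelled 30 min replicate 2 and -0.83 without both. The respiratory list there had -0.01 without the suffix arrays and 0.02 without the array labelled 30 min replicate 2 or both, and the proteasome -0.14 and -0.16 without the arrays labelled 0 min replicate 1 and 30 min replicate 1. In the interaction at 30 min, ribosome biogenesis had 0.14, 0.18 and 0.61 without the array labelled 0 min replicate 2, that labelled 30 min replicate 2, or both. Without both, ribosomal proteins had 0.03, Msn2/4 genes -0.18, translation factors 0.15 and G1/S genes 0.06. The other ends of these ranges over the arrays left out were 0.44, -0.77 and 0.46 for ribosomal proteins, Msn2/4 genes and translation factors between the strains at 0 min, and -0.48, -0.66, 0.81 and 0.76 for ribosomal proteins, ribosome biogenesis, Hsf1 chaperones and Msn2/4 genes at 30 min. They were 0.54, -0.11 and 0.19 for ribosome biogenesis, the respiratory list and the proteasome in the wild type at 30 min, 0.49 for ribosomal proteins there at 75 min, and -0.7 for ribosome biogenesis in the interaction at 30 min.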

Other observations

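Several gene groups outside the main themes held members that differed between the strains at 75 min, while camera called none of their lists with all arrays. Core histone genes were higher in 3 of 7, with HTA1 at 0.4 log2 units (SE 0.09), and 4 were higher adjusted over the list alone (median 0.2, camera adjusted p = 0.12). G2/M genes were higher in 3 of 12, as over the list alone (median 0.39, camera adjusted p = 0.079), and 7 were higher when the 2 wild-type arrays set aside were left out (camera adjusted p = 0.021). Among 7 a-cell genes 2 were higher, including BAR1, the protease that degrades alpha-factor, at 1.43 (SE 0.14), with 2 higher and 1 lower adjusted over the list alone (median -0.1, mean 0.06, camera adjusted p = 0.72). Stationary-phase genes were lower in 2 of 7, as over the list alone, SIP18 at -1.72 (SE 0.35) and SPG4 at -0.87 (SE 0.13), with a median of -0.77 (camera adjusted p = 0.17). Iron regulon genes were higher in 5 of 18 and lower in 2, as over the list alone (median 0.29, camera adjusted p = 0.33), with the copper chaperone gene ATX1 at -1.61 (SE 0.12). Of 16 glycolysis genes 1 was higher and 2 lower, as over the list alone (median 0, camera adjusted p = 0.87), with the phosphofructokinase gene PFK2 at -0.68 (SE 0.1).

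Smaller movements were seen in the remaining lists at 75 min between the strains. In the unfolded protein response 2 of 14 were higher and 3 lower, as over the list alone (camera adjusted p = 0.82), and among sporulation genes 2 of 14 were higher and 3 lower, as over the list alone (camera adjusted p = 0.94). Haploid genes had 2 higher and 1 lower of 9, as over the list alone (camera adjusted p = 0.75). G1/S genes had 2 higher and 2 lower of 19, with 1 and 2 over the list alone (camera adjusted p = 0.82), and TCA cycle genes 2 higher and 1 lower of 16, with 1 and 0 over the list alone (camera adjusted p = 0.65). Copper-regulated genes had 1 higher and 1 lower of 7, as over the list alone (camera adjusted p = 0.74), and translation factors 1 lower of 25 with 0 over the list alone (camera adjusted p = 0.46). None of 6 GAL genes was called (median -0.11, camera adjusted p = 0.75), and in nab2-td 4 of the 6 were higher at 30 min than at 0 min (median 0.33, camera adjusted p = 0.081; 0.03 without the arrays set aside). Without those arrays, 8 translation factor genes were higher and 1 lower between the strains at 75 min, 5 G1/S genes were higher and 3 lower, 3 copper-regulated genes were higher, and 3 TCA cycle genes and 4 stationary-phase genes were lower.

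The span of a gene from start to stop was not a multiple of 3 for 164 of 5446 genes, a stand-in for interrupted genes that misses those whose introns keep the frame. Between the strains at 75 min, 66 of these were lower and 8 higher in nab2-td, with a median of -0.22 against 0.03 for the other 5282. The 110 that do not encode ribosomal proteins had a median of -0.44. Among genes spanning at most 660 bases the medians were -0.82 and -0.24. Among the 10 named lowest genes, 4 had such a span at 75 min (OST5, NCE101, VMA9 and DYN2) and 4 at 30 min (UBC12, HMRA1, GPI15 and NCE101), against 1 of the 10 highest at each time. These counts were chosen after seeing the data and were not tested.

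Within single arrays, gene length correlated with the level relative to the mean of all arrays at 0.078 to 0.154 (Spearman) in the 6 nab2-td arrays of 30 and 75 min, and at -0.177 to -0.007 in the other 9. The control probe sets for ribosomal RNA averaged 10.84 log2 units (SD 0.03) in the wild type and 10.47 (SD 0.4) in nab2-td at 75 min, against 11.87 (SD 0.62) and 11.68 (SD 0.24) at 0 min. The mean 3′ minus 5′ difference of the control genes was 1.52 in nab2-td 30 min replicate 3, and lay between 0.94 and 1.09 in the other 14 arrays.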
